A study of Homo sapiens with 2 samples.

How the data were processed

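Gene expression was measured in MDA-MB-231 cells, an established human line of triple-negative breast cancer, 24 h after transfection with a control vector or with a vector that expresses BRMS1L. BRMS1L is a homologue of the metastasis suppressor BRMS1 and belongs to the SIN3-HDAC corepressor complex. Each group had 1 array, so 2 arrays were compared. Per the labels' protocols, total RNA was copied into cDNA from oligo-dT primers, labelled with Cy3 and hybridised to 1-colour NimbleGen expression arrays.

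The deposited values were intensities on a linear scale, 1 per transcript feature and array. RMA, which corrects background, normalizes between arrays and summarises the probes of a feature, is named in the submitters' processing notes. Its version and settings, the genome build and the position of the probes are not given in the sources used here. The table held 35209 features, and none was under 100 on either array, with minima of 100.01 on the control array and 100.07 on the BRMS1L array. A transcript that was bright on 1 array and under 100 on the other would therefore not be seen here. No scanner signals, detection calls or probe values were used.

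Features were named through an annotation table of the platform (14194 features) and, by RefSeq accession without its version, through a RefSeq gene table of GRCh38.p14 (546 more). In this way 14740 features were assigned to 1 gene each and gave 13469 genes. The other 20469 features, mostly GenBank and predicted RefSeq entries, are unnamed here, and 0 features matched several genes. Where a gene had several features (1030 genes), the feature with the highest mean level represented it. Symbols are those of the RefSeq table, and older symbols in the gene lists were updated through its synonyms.

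Intensities were converted to log2, with a floor of 1 that no value reached, and the log2 difference was taken as the BRMS1L array minus the control array. With 1 array per group no test, p-value or standard error between conditions can be had, and a statement on a gene compares 2 arrays. A gene was counted when the arrays differed at least 2-fold and its higher value was at or above the median of all features, an intensity of 1088. This left 7113 genes. For lists of genes, the median log2 difference was set against 10000 random lists of the same size drawn from genes of like level, in 20 level classes of equal size. A list stands apart at or below the 2.5th or at or above the 97.5th percentile, and lists with fewer than 5 measured genes got no percentile. A percentile describes these 2 arrays and is not a p-value for the conditions.

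Chosen before the data were examined were 35 gene lists, the thresholds, the alternatives and the rule for named genes. That rule takes BRMS1L and FZD10, the 12 genes with the largest positive and the 12 with the largest negative difference at or above the 75th percentile of level (an intensity of 3319), and up to 4 members of a list with the largest absolute difference at or above the median level. In the 12 and 12, 0 symbols of uncharacterised loci were passed over. Genes named outside the rule are marked as such, and 1 gene that the rule takes is not reported here.

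The number of arrays limits the precision. As a technical yardstick, 870 genes with exactly 2 features gave a single-feature SD of 0.21 log2. It measures how far the differences of the 2 features of a gene lay apart on the same arrays. The differences of the 2 features of a gene correlated with Pearson's r of 0.24 and Spearman's rho of 0.21 across genes, which are not independent replicates, and such features can share probes. The spread of the differences depended on level. Its SD across genes was 0.39 log2 in the dimmest level class of 10 and 0.16 in the brightest. The list method was tested on simulated data with the levels of these 13469 genes. Differences were shuffled within level classes, so the simulated genes varied independently. Real genes of a list can vary together, and the rates that follow need not hold for them. Of 200 simulated lists of 20 unchanged genes, 3.0% were called low and 3.5% high. A list shifted by 0.1 log2 was called high in 38.5% of 200 simulations, one shifted by 0.2 in 90.0% and one shifted by 0.3 in 100%.

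The alternatives were centring on a loess curve of difference on level (span 0.3), median centring, quantile normalization, the mean of a gene's features, 16 added before log2, other filters and fold thresholds, 10 level classes and the mean of a list. Matching on neighbouring genes (2 on each side, 3 classes) and counting all features were added after seeing the data. FZD10 was not analysed here. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.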

Results

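The study asked what BRMS1L, a subunit of the SIN3-HDAC corepressor complex, changes in the transcriptome of metastatic breast cancer cells, and its title names the WNT receptor gene FZD10 as a silenced target. Expression was compared between 1 array of MDA-MB-231 cells transfected with a BRMS1L vector and 1 array of cells transfected with a control vector, both at 24 h. There were no replicates, so no difference below has an error between cultures or a p-value. The median intensity was 1077 on the control array and 1098 on the BRMS1L array over 35209 features, and the log2 values of the arrays correlated with Pearson's r of 0.99 across features, which are not independent replicates. The median log2 difference of all features was 0.03. The disagreement between the 2 features of a gene on these arrays gave an SD of 0.21 log2 per feature, which holds no error between cultures.

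BRMS1L itself was higher on the array of cells that received its vector, but dim on both. Its feature (NM_032352) read 142 on the control array and 227 on the BRMS1L array, a log2 difference of 0.68 or 1.60-fold. This was higher than in 93.5% of the 673 genes of like level, whose differences had an SD of 0.43, and 142nd from the top among 13469 genes. The sources used here do not say whether the probes of this feature lie within the insert of the vector, so the value neither bears out nor contradicts the labels. The largest difference on the arrays belonged to a feature without a gene name here, BC006250, which read 423 on the control array and 28727 on the BRMS1L array. That is a log2 difference of 6.09, or 67.9-fold, and the feature moved from above 27.4% of the features on the control array to above 99.1% on the BRMS1L array. The next largest difference of the 35209 features was 2.26, or 4.79-fold. FZD10, a Frizzled receptor for WNT ligands, was not analysed here.

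Few named genes differed by a large factor. Of 7113 genes at or above the median level, 0 were at least 2-fold higher on the BRMS1L array and 2 were at least 2-fold lower. These were MAGEA4, a cancer-testis antigen, at 1177 on the control array against 478 (2.46-fold lower), and SMR3A, a salivary gland protein gene, at 2040 against 976 (2.09-fold lower). SMR3A falls outside the naming rule and was chosen after its values were seen. At 1.5-fold the counts were 19 higher and 40 lower. With no filter on level, 15 of 13469 genes were at least 2-fold higher and 27 at least 2-fold lower. The largest of these were also chosen after their values were seen. They were the zinc finger gene ZFP2, 4.79-fold higher (118 against 566), PKD2L2, a polycystin family channel gene, 3.03-fold higher (164 against 497), and the olfactory receptor gene OR51Q1, 3.03-fold lower (414 against 136). All 3 were dim, in level classes where the SD of the differences across genes was 0.39 to 0.41 log2.

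Among the brighter genes, at or above the 75th percentile of level, ZFP91 and TAF15 had the largest positive differences. ZFP91, which encodes a zinc finger ubiquitin ligase, was 1.64-fold higher (2430 on the control array against 3980). TAF15, a FET family RNA-binding protein, was 1.61-fold higher (8930 against 14358). The mitochondrial genes ATP5PO, an ATP synthase subunit, and UQCRFS1, the Rieske protein of complex III, were 1.43-fold and 1.42-fold higher. CXCL8, the neutrophil chemokine interleukin-8, was 1.43-fold higher (4141 against 5915), and TRAF3IP2, an adaptor of the interleukin-17 receptor, 1.40-fold. SPG21 was 1.48-fold higher, ARLN 1.48-fold, the gamma-secretase subunit APH1A 1.44-fold, the spindle checkpoint gene BUB3 1.43-fold, the glyoxalase gene HAGH 1.42-fold and the phosphatidylinositol synthase gene CDIPT 1.41-fold. The log2 differences of these 12 genes ran from 0.48 to 0.71.

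On the lower side of the same level range, FGFBP3 and F2RL3 had the largest differences. FGFBP3, a fibroblast growth factor binding protein, was 1.84-fold lower (5863 on the control array against 3180). F2RL3, the thrombin receptor PAR4, was 1.69-fold lower (4762 against 2817). FOXC2, a forkhead transcription factor of mesenchymal cells, was 1.61-fold lower (5083 against 3150). The splicing factor PRPF19 was 1.58-fold lower (15383 against 9765). The hair keratin-associated gene KRTAP12-4 was 1.65-fold lower and the metallothionein MT1E 1.59-fold, and both have near-identical relatives whose transcripts can bind the same probes. The laminin receptor BCAM was 1.53-fold lower, a log2 difference of -0.62 that became -0.36 as the mean of its 2 features. ZSCAN2, a zinc finger gene, was 1.53-fold lower, with -0.61 against -0.31 as the mean of 3 features. The platelet lectin CLEC1B was 1.53-fold lower, the complex I subunit NDUFA11 1.45-fold, TTC7A 1.42-fold and PPP1R26 1.41-fold.

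**Figure D1:**
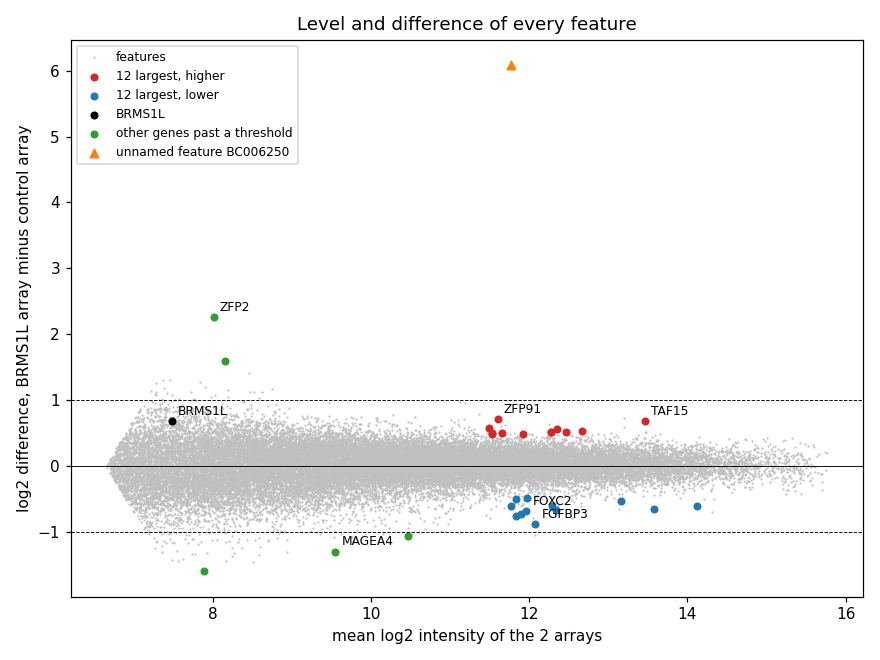
The log2 difference (BRMS1L array minus control array) of each of the 35209 features is plotted against the mean log2 intensity of the 2 arrays. Dashed lines mark 2-fold. BC006250 lies at 6.09, far above the next feature at 2.26, and BRMS1L lies at 0.68 among dim features, whose differences scatter more widely than those of bright features.

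Of 34 gene lists with at least 5 measured genes, 3 stood apart from matched random lists, where 1.7 would by chance if genes varied independently. These were the WNT ligands and secreted WNT inhibitors and the neuronal genes, both lower on the BRMS1L array, and the cytoplasmic ribosomal protein genes, which were higher. Of 17 WNT ligand and inhibitor genes measured, 13 were lower and 4 higher on the BRMS1L array, with a median log2 difference of -0.18 (percentile 0.91). This pooled set is called the WNT ligand list below. WNT7A read 513 on the control array against 235 (-1.13), WNT10B 331 against 203 (-0.71), and WNT2B 548 against 364 (-0.59), all dim genes named after their values were seen. Of the dim secreted inhibitors, named in the same way, DKK4 was at 0.49, SFRP2 at 0.32 and SFRP5 at -0.26. Only 4 of the 17 were at or above the median level. Among these WNT9A differed by -0.18, WNT5B by 0.11, WNT7B by -0.002 and DKK1, a secreted WNT inhibitor, by 0.04. Of 13 measured neuronal genes known as targets of the repressor REST, 10 were lower and 3 higher, with a median of -0.22 (percentile 0.37), and 5 of the 13 were at or above the median level. Synaptophysin (SYP) was at -0.31, the adhesion molecule L1CAM at -0.28 and syntaxin STX1A at -0.22, whereas VGF was at 0.16 and the dim synaptotagmin SYT4, also named after its value was seen, at 1.12. The neuronal list no longer stood apart with the mean of the list (percentile 9.22) or with the mean of each gene's features (9.69).

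The list of Frizzled and LRP receptors, taken without FZD10, did not stand apart. It also holds the WNT receptors ROR1 (-0.07), ROR2 (-0.19) and RYK (0.02). Of 13 measured genes in the list, 8 were higher and 5 lower, with a median of 0.06 (percentile 59.2). FZD6 was 0.62 higher (862 on the control array against 1324), FZD4 0.30 and LRP5 0.16, while LRP6 was at -0.12. Genes driven by beta-catenin were evenly divided, 8 higher and 8 lower, with a median of 0.01 (percentile 35.6). Cyclin D1 (CCND1) was at 0.25 and MYC at 0.24, while the transcription factor TCF7L2 was at -0.32 and the pathway inhibitor NKD1 at -0.21. In the SIN3-HDAC complex itself, 14 of 19 genes were higher and 5 lower, with a median of 0.09 (percentile 78.9). MORF4L1 was at 0.37, RBBP4 at 0.19 and BRMS1 at 0.15, and PHF12 at -0.16. Notch pathway genes had a median of 0.02 (percentile 38.0), with NOTCH2 at 0.34 and its ligand JAG2 at -0.13.

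Neither side of the epithelial to mesenchymal transition stood apart from random lists. Of 18 mesenchymal genes, 11 were lower and 7 higher, with a median of -0.03 (percentile 12.5). FOXC2 was at -0.69, N-cadherin (CDH2) at -0.43 and the transcription factor SNAI1 at -0.37. Of 16 epithelial genes, 10 were lower and 6 higher, with a median of -0.05 (percentile 8.50). P-cadherin (CDH3) was at -0.50 and desmoplakin (DSP) at -0.46, ELF3 at -0.19 and MUC1 at 0.24. Matrix proteases and their inhibitors had a median of 0.11 over 17 genes (percentile 88.1). The inhibitor TIMP3 was at 0.29, ADAM17 at 0.27 and MMP14 at 0.21, while the collagenase MMP1 was at -0.29. Integrins had a median of 0.04 (percentile 57.9), with ITGA7 at -0.68, ITGA5 at 0.41 and ITGA2 at 0.35. With only genes at or above the median level the integrins reached percentile 97.52. Extracellular matrix genes had a median of 0.04 (percentile 51.9), with COL4A2 at 0.32 and fibronectin (FN1) at -0.23. TGF-beta response genes had a median of 0.02 (percentile 30.4), with ID3 at 0.22 and CCN2 at -0.19.

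Cytoplasmic ribosomal protein genes were slightly higher on the BRMS1L array. Of 35 measured genes 25 were higher and 10 lower, with a median log2 difference of 0.11, or 1.08-fold (percentile 99.8). RPL4 was at 0.30, RPL7 at 0.29, RPL18 at 0.28 and RPL5 at 0.26, and 0 of the 35 reached 1.5-fold. Many of these genes have processed pseudogenes of near-identical sequence. Oxidative phosphorylation genes had a median of 0.06 (percentile 69.5), with ATP5PO at 0.52, COX6C at 0.35 and UQCRQ at 0.32. With the mean of the list they stood apart (98.4). Glycolysis genes had a median of 0.08 (percentile 86.1), with TPI1 at 0.32, LDHA at 0.30 and ENO2 at -0.38. Hypoxia genes had a median of 0.14, with 14 of 18 higher and a percentile of 97.0 that lay just inside the limit. The carbonic anhydrase gene CA9 was at 0.36 and the collagen prolyl hydroxylase genes P4HA1 and P4HA2 at 0.26 and 0.25. Cholesterol synthesis genes had a median of -0.01 (percentile 10.3), with SQLE at 0.51 and NSDHL at -0.32.

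NF-kB target genes were mostly higher on the BRMS1L array, 17 of 22 with a median of 0.12, at a percentile of 95.7 that did not reach the limit. CXCL8 was at 0.51, the feedback inhibitor TNFAIP3 at 0.39 and CXCL1 at 0.36, and TRAF1 at -0.36. The list did stand apart with only genes at or above the median level (percentile 98.2) and with the mean of the list (99.2). Interferon-stimulated genes, which can respond to transfected DNA, had a median of 0.10 over 26 genes (percentile 85.9), with IFI6 at 0.56 and OAS1 at 0.36. Interferons and their chemokines had a median of -0.003 over 5 genes (percentile 46.8), which was the value of CCL5. Immediate early genes had a median of 0.01 (percentile 25.6), with KLF2 at 0.71 and KLF4 at 0.29. Genes of the unfolded protein and integrated stress responses had a median of 0.11 (percentile 89.2), with DDIT3 (CHOP) at 0.52. Heat shock genes had a median of -0.001 (percentile 27.3), with HSPH1 at 0.37 and HSPA8 at -0.27. The value of HSPA8 was -0.01 as the mean of its features.

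Proliferation genes differed little between the arrays. S phase genes had a median of 0.02 over 23 genes (percentile 30.1), with the histone mRNA binding protein SLBP at 0.41 and thymidylate synthase (TYMS) at -0.40. G2 and mitosis genes had a median of 0.005 over 26 genes (percentile 19.96), with CCNB2 at 0.31 and CDK1 at 0.28. Targets of p53 had a median of 0.04 (percentile 47.6), with PHLDA3 at -0.33, TP53I3 at 0.19, BAX at -0.18 and CDKN1A at -0.13. Histone genes, whose mRNA mostly lacks a poly(A) tail, had a median of 0.07 (percentile 66.4), with H4C3 at 0.31 and H1-4 at -0.25. Housekeeping genes had a median of 0.04 (percentile 53.2), with ACTB at 0.43 and EEF1A1 at 0.35. Cancer-testis genes had a median of -0.05 (percentile 33.0), and the 2 of them at or above the median level were MAGEA4 at -1.30 and CTAG1A, which has a near-identical copy, at -0.66.

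Markers of other cell types gave no list that stood apart. Basal or myoepithelial markers had a median of -0.14 over 9 genes, at a percentile of 2.72 that just missed the limit. It crossed the limit in 2 of 8 alternatives, at 2.11 with loess centring and 2.41 with the mean of each gene's features. It rose to 3.17 with the mean of the list and to 4.06 with matching on neighbouring genes. CDH3 was at -0.50, KRT6B at -0.20, S100A2 at -0.14 and KRT5 at 0.01. Luminal markers had a median of -0.09 (percentile 7.58), with MLPH at -0.09 and XBP1 at 0.11. The medians were -0.04 for fibroblasts (percentile 38.8), 0.05 for leukocytes (58.5) and -0.13 for erythroid cells (18.5), and 0.08 for 3 endothelial genes, too few for a percentile. The median and the mean differed in sign in 5 lists, those of beta-catenin targets, integrins, interferons, cholesterol synthesis and leukocytes. The medians of 7 lists, at most 0.04 in size and so open to a small shift of all genes, changed sign under a centring or quantile normalization, namely beta-catenin targets, extracellular matrix, TGF-beta response, Notch, S phase, G2 and mitosis, and immediate early genes.

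**Figure D2:**
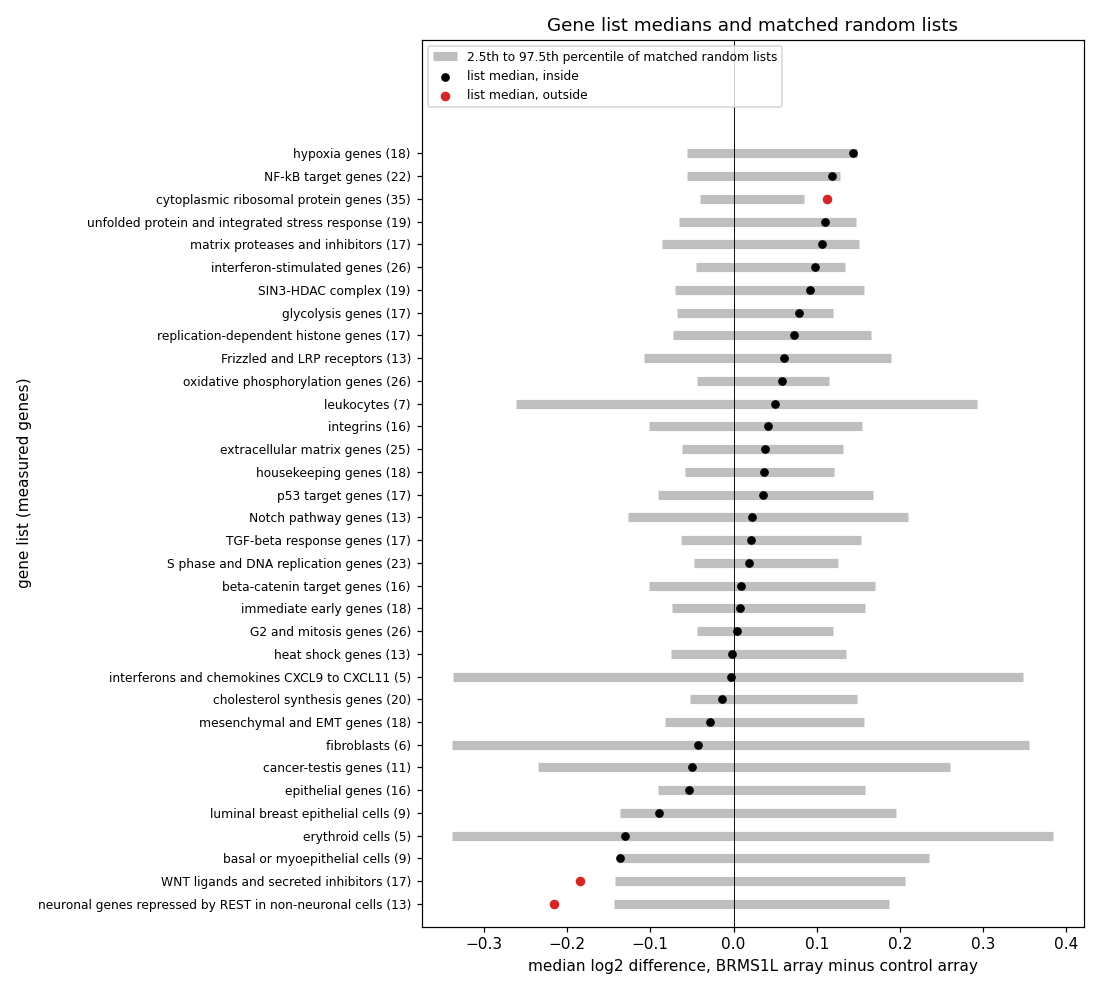
Each point is the median log2 difference (BRMS1L array minus control array) of 1 of 34 gene lists, with the number of measured genes in brackets, and each grey bar spans the central 95% of 10000 random lists matched on level. The neuronal list (-0.22) and the WNT ligand list (-0.18) lie left of their bars and the cytoplasmic ribosomal protein list (0.11) lies right of its bar.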

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

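The test of the unnamed feature was chosen after its value was seen. Feature BC006250, which the gene counts and lists do not use because it has no gene name here, was 6.09 log2 higher on the BRMS1L array than on the control array (28727 against 423), a signal far above its control level. A candidate explanation is that it reads the transcript made from the vector. BRMS1L's own feature differed by 0.68, which leaves that open, because nothing used here says which part of a transcript either feature reads. A fault of this 1 feature on 1 array also stays open, since values of single probes were not used here. Without a gene name or a replicate array these explanations cannot be told apart.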

How the results depend on the processing

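The count over all features and the matching on neighbouring genes were chosen after seeing the data. The count of 2 genes at least 2-fold apart, both lower on the BRMS1L array, was 2 or 3 under loess centring, median centring, quantile normalization, the mean of a gene's features and 16 added before log2, with 0 genes higher in each. It depended on the filter and threshold by construction. It was 42 with no filter on level (15 higher, 27 lower), 0 with a filter at the 75th percentile, 59 at 1.5-fold (19 higher, 40 lower) and 0 at 3-fold. Over all features it was 102 (31 higher, 71 lower), which changes 2 choices together, no filter and the counting of unnamed features (58 of the 102) and of several features of a gene. BRMS1L kept a positive difference, from 0.62 to 0.71. The number of lists standing apart was 3 or 4 under all 9 alternatives. The ribosomal protein list stood apart in all 9 (percentiles 99.2 to 99.9), the WNT ligand list in all 8 that gave it a value (0.45 to 2.17) and the neuronal list in 7 of 9 (0.26 to 9.69). Of 299 alternative list percentiles 8 crossed a limit. Median centring is among these alternatives but shifts all genes alike, so it could not move a percentile and its values test nothing. Loess centring removes a trend with level that the matched random lists already share, so it tests a percentile only weakly. For the ribosomal protein list, 34 of 35 genes were at or above the median level. The filter at that level and the 16 added before log2 could therefore change its percentile little. Of 750 alternative values of 150 named genes, 3 moved by more than the single-feature SD and 0 of those past 1.5-fold changed sign. Many of the 750 could not move that far. The shift of median centring was 0.03 for every gene, and the mean of features leaves genes with 1 feature unchanged. Leaving out a replicate was not possible, with 1 array per group. No paired analysis was possible because each group has 1 array. FZD10 was not analysed here and so has no alternative values. Signal limits dim genes most, since the SD of the differences was 0.39 log2 in the dimmest level class and 0.16 in the brightest.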

Other observations

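The gene families here were chosen after values were seen, as were the tests of level trends and of unexpressed, dim, neighbouring and broadly expressed genes. The test of genes with 2 features was set out before its result was seen. Of 21 gene families drawn by symbol, 3 stood apart high and 8 low against matched random lists. Mitochondrial ribosomal protein genes were higher on the BRMS1L array in 59 of 77 cases, with a median log2 difference of 0.13 (percentile 99.96). The wider set of 85 cytoplasmic ribosomal protein genes had a median of 0.08 (percentile 99.7), and 9 genes of the chaperonin that folds actin and tubulin had 0.18 (98.3). Proteasome genes had 0.04 (56.0) and initiation factor genes 0.03 (34.5), the latter with a sign that changed under loess centring and quantile normalization.

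The 8 low families were dim at their median, but not all dim families were low. Kallikrein-related peptidases had a median of -0.45 over 9 genes (percentile 0.04), late cornified envelope genes -0.32 over 11 (0.24), beta-defensins -0.28 over 9 (1.59), keratin-associated proteins -0.27 over 49 (0.00), HOX genes -0.22 over 23 (0.16), olfactory receptors -0.22 over 121 (0.00), potassium channels -0.13 over 49 (0.50) and GPR receptors -0.07 over 48 (1.92). Their median intensities ran from 217 to 628, against 1088 for all features, and all 8 medians stayed negative under the centrings and quantile normalization. The dim MAGE, interleukin and protocadherin families were not low, with medians of 0.08, 0.02 and 0.01 (percentiles 74.995, 35.8 and 41.1), of which the last 2 changed sign under a centring or quantile normalization.

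For the lower WNT ligand and neuronal lists, a level-dependent normalization trend is argued against as the whole cause, since the medians of level classes ran only from -0.03 to 0.07 and the list medians were -0.22 and -0.18 before and, for the neuronal and the WNT list, -0.22 and -0.20 after a loess curve on level was removed. Dimness was examined for the neuronal list alone. Its 5 members at or above the median level had a median of -0.22 against 0.05 for all such genes (percentile 0.33). These members belong to a list singled out for its low median, and STX1A is the median gene of the list and of the 5. The value therefore cannot decide, and dimness stays open. The 5 genes were SYP at -0.31, L1CAM at -0.28, STX1A at -0.22, TUBB3 at -0.08 and VGF at 0.16. With the mean of each gene's features the whole neuronal list did not stand apart (percentile 9.69). A lower signal of unexpressed genes stays open, since 21 genes of the fibroblast, endothelial, leukocyte and erythroid lists went both ways (11 lower, median -0.02, SD 0.27, percentile 29.3, 3 at or above the median level), while olfactory receptor, keratin-associated protein and late cornified envelope genes, pooled after they were seen to be low, were lower in 143 of 181 cases (median -0.25). The difference of a gene followed that of its neighbours on the chromosome (Spearman's rho of 0.17 across genes, highest of 100 shuffles 0.04), and with random lists matched on 3 classes of the neighbours' difference the percentiles were 0.57 and 2.17, still inside the low limit, but base composition was not measured here and a trend with it stays open. An effect of the BRMS1L vector also stays open, as untested with 1 array per group. So does chance among the 34 lists, of which 3 stood apart where 1.7 would by chance if genes varied independently.

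The median of the ribosomal protein list was 0.112 before and 0.091 after a loess curve on level was removed, which argues against a level-dependent trend as the whole cause. By the median alone, a higher signal of all broadly expressed genes is argued against too. The 106 genes of 5 other lists had a median of 0.04 (95% bootstrap interval 0.01 to 0.07 over genes) at percentile 62.4. This was below the 0.11 of the ribosomal list and the 0.08 of the wider set of 85 genes. By the mean, oxidative phosphorylation (0.109), glycolysis (0.101) and housekeeping genes (0.086) came near the ribosomal list (0.099). S phase (0.022) and mitosis genes (0.038) did not. The means therefore do not set the ribosomal list apart from the first of these groups. A higher signal of some such groups stays open, since mitochondrial ribosomal protein and chaperonin genes were higher too and spliceosomal SNRP genes had a median of 0.14 (percentile 95.4). Binding of pseudogene transcripts, a difference between the cultures or RNA preparations and an effect of BRMS1L were not tested.

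The differences of 2 features of a gene correlated at 0.24 across genes, between the bounds of 0.1 and 0.3 set beforehand for noise of single features and against it.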
